A study of Mus musculus with 9 samples.

How the data were processed

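RNA was measured by bulk sequencing in 9 libraries, 3 from each of 3 groups. GL261 is a mouse glioblastoma line. The tumour group came from brains of immunocompetent mice resected 14 days after 50000 GL261 cells were implanted in the striatum, in 5 mice per the labels' protocols. Both culture groups held a penta-culture of GL261 with primary mouse astrocytes, microglia, pericytes and endothelial cells, either on a dish (2D culture) or in a fibrin gel (3D bioink), with GL261 seeded at 1000000 cells per ml. The labels' protocols record that primary cells were sorted from mouse brain with magnetic beads against CD11b for microglia, CD31 for endothelial cells and AN2 and CD144 for pericytes, and that the cells left over served as astrocytes. Digestion before RNA isolation is recorded for the 3D bioink only. It used collagenase II at 600 U per ml for 3 h, followed by a mesh filter. Libraries were made from 25 to 75 ng of total RNA with a strand-specific kit and 14 PCR cycles, per the labels' protocols. The labels do not say whether the 3 tumour libraries came from 3 mice, or whether the 3 culture libraries of a group came from separate cultures.

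The deposited table holds 1 score per gene symbol and library, a normalized count that the authors rounded to whole numbers. Per the submitters' processing notes, kallisto, RSEM, DESeq2 1.24.0, DESeq and the mouse build mm10 were used. The notes give neither the role nor the order of these tools, nor whether reads were assigned by strand, so overlapping or antisense genes cannot be told apart in these values. The read depth of each library is unknown. The deposited values summed to between 16320090 and 16388074 in the tumour libraries, 15572800 and 15711632 in 2D culture, and 13548461 and 13683978 in 3D bioink. These sums follow the normalization and are not depths, so no counting interval or detection limit is given, and a gene with no signal is said to be listed at 0. Genes with near-identical copies, among them H2-Q4, Hspa1a, C4b, Prl2c2, histones and ribosomal proteins, are uncertain, because reads may have been split between copies. Gene coordinates are those of GRCm38.p6, the assembly also called mm10.

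All tests started from log2(value + 1). Of 20778 symbols, 2865 were 0 in all 9 libraries, and the 13773 with a mean of at least 10 over the 9 libraries were tested. A single limma model (version 3.58.1, R 4.3.3; lmFit, contrasts, and eBayes with a trend) was fitted to all 9 libraries, and every adjusted p for a gene is limma's, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. These p-values measure the spread between these libraries, which may be technical. On simulated data with 200 genes of 13773 changed by 1 on the log2 scale, the model recovered 52% of them for 3D bioink against tumours, 49% for 2D culture against tumours and 57% for 3D bioink against 2D culture. For a change of 0.5 it recovered 23.5%, 25% and 22.5%, and for a change of 2 it recovered 82%, 81% and 82%, in the same order. Each of these 9 simulations gave between 1 and 11 false calls. The real comparisons called 54.3% to 64.4% of genes, far more than the 200 changed here. The adjusted threshold was therefore stricter in the simulations, and these rates need not hold for the real data.

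The design, the threshold, the alternatives, the gene lists and the rule for named genes were set before the data were examined. There were 38 lists, 14 of cell type markers and 24 of programmes, taken from general knowledge and not from these libraries. Of their 569 entries, 567 were in the table and 501 were tested. Each list was tested in the 3 comparisons with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 114 tests. Camera with an estimated correlation and fry (limma) were run beside it. For each list the members past the per-gene threshold were counted, and counted again with p adjusted over the list alone. List medians are given also without members listed at 0 in all 3 libraries of a compared group, where there were any. The rule for named genes took, for each comparison, the 5 largest rises and 5 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 100 in the higher group. To these it added 2 members, and the strongest opposite member, of each of the 8 lists with the smallest p, and a fixed set (Gfap, Tmem119, Cdh5, Pdgfrb, Cd3e, Snap25, Mbp, Col1a1, Mki67, Vegfa, Selp, Fos, Hspa1a and Cd274). Other genes that the text names were chosen after their values were seen.

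The distance of a library to the tumours was the root mean square log2 difference from the mean of the 3 tumour libraries over all tested genes. The 2 cultures were compared by an exact two-sided permutation test over 20 assignments of 6 libraries, for which the smallest possible p is 0.1. The overlap of the comparisons that share the tumour libraries was set beside 20 simulated sets with no group effect. Alternatives covered the pseudocount, the filter, 3 other scalings, a fit of the compared groups alone, a block for the replicate number, array weights, no trend, a 2-fold minimum, leaving out each library, and other distance measures. Further alternatives and lists were chosen after seeing the data and are named as such. A test on counts could not be run, because the values are not counts. Values in the text are deposited normalized values, given as mean ± SD with n = 3 per group. Plots used Python 3.11.15 with matplotlib 3.10.9.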

Results

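The series compared GL261 glioblastoma grown in mice with GL261 grown beside brain cells in 2D culture or in a 3D fibrin bioink, with 3 libraries in each of the 3 groups. The values are normalized counts per gene as deposited, and the read depth behind them is unknown. Each library is a mixture of cells, so a value describes the mixture and not GL261 alone. Across genes, the correlation of log2 values between libraries of a group was 0.940 to 0.943 for tumours, 0.968 to 0.970 for 2D culture and 0.927 to 0.963 for 3D bioink. Between groups it was 0.863 to 0.903 for 2D culture with 3D bioink, 0.790 to 0.797 for tumours with 2D culture and 0.744 to 0.794 for tumours with 3D bioink. The 3D bioink library of replicate 1 stood apart, with the lowest array weight of the 9 (0.236, against 0.688 to 4.96 for the others).

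The first comparison asked how the 3D bioink differed from the tumour in the animal. Genes of antigen presentation, microglia, macrophages and complement were far lower in the bioink, and genes of basement membrane, interstitial matrix and cholesterol synthesis were higher. Cd74, the invariant chain of MHC class II (chromosome 18, 60803849 to 60812652 in GRCm38), stood at 64270 ± 2980 in tumours and 32 ± 7.94 in bioink (n = 3 each). That is 1982-fold lower, with a log2 fold change of -10.95, SE 0.28 and adjusted p = 2.18e-09. Mmp3, a secreted matrix metalloproteinase (chromosome 9, 7445822 to 7455975), rose from 10 ± 5.29 to 5823 ± 146 (n = 3), 569-fold higher (log2 9.15, SE 0.38, adjusted p = 4.58e-08).

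The other genes with the largest rises in the bioink were Ereg, an EGF receptor ligand, from 4.33 ± 5.86 to 1466 ± 126; the collagen cross-linking enzyme Lox, from 8.67 ± 8.51 to 2327 ± 271; and Cyp1b1, a cytochrome P450, from 2 ± 1.73 to 769.67 ± 57.0 (n = 3 each). Their log2 fold changes were 8.79, 8.68 and 8.25, but rested on low tumour values, 0, 11 and 2 for Ereg and 0, 9 and 17 for Lox. Without tumour replicate 1 they were 7.93 for Ereg and 7.43 for Lox, without replicate 2 9.72 for Ereg, and without replicate 3 9.52 for Lox and 7.59 for Cyp1b1. Grem1, a secreted BMP antagonist, was listed at 0 in all 3 tumour libraries and at 292, 285 and 316 in the bioink libraries. The largest falls besides Cd74 were in H2-Aa, a chain of MHC class II, from 12417 ± 351 to 4.67 ± 5.51, and in Fcer1g, an adaptor of Fc receptors, from 3414 ± 117 to 0.667 ± 0.577. Il1b, the cytokine interleukin 1 beta, went from 8636 ± 251 to 4.33 ± 3.21, and the complement subunit C1qc from 10685 ± 266 to 8 ± 4.58 (n = 3 each). The log2 fold changes of these 4 genes lay between -11.54 and -10.38, with H2-Aa at -12.31 without bioink replicate 2. They depend on the 1 added before taking logs, because the bioink values were near 0.

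Immune gene lists were lower in the bioink than in the tumours. All 21 interferon response genes fell (median log2 fold change -2.27, camera adjusted p = 1.41e-10), among them the chemokine Cxcl9, from 1579 ± 77.7 to 14.7 ± 10.0, and Oasl1, from 980.33 ± 91.1 to 40.3 ± 14.3 (n = 3). In MHC class I and antigen processing, 12 of 13 genes fell and 1 did not pass (median -3.55, adjusted p = 1.87e-08). Psmb9, a subunit of the immunoproteasome, went from 2356 ± 37.2 to 103 ± 6.43 (n = 3). Nlrc5, which activates MHC class I transcription, went from 1579 ± 877 to 64 ± 32.4 (n = 3). All 8 MHC class II genes fell (median -6.35, -5.57 without the member listed at 0, adjusted p = 6.99e-05). Complement genes fell in 12 of 13 cases and rose in 1 (median -3.30, adjusted p = 3.87e-05). Of 21 cytokines and chemokines, 16 fell, 2 rose and 3 did not pass (median -4.82, adjusted p = 0.000506; adjusted p = 0.0557 with an estimated correlation). Of 12 immune checkpoint genes, 9 fell (median -3.53, -3.31 without the member at 0, adjusted p = 0.000944; adjusted p = 0.0501 with an estimated correlation). Cd274, which encodes PD-L1, fell from 4411 ± 139.5 to 206 ± 7.81 (n = 3; log2 -4.41, SE 0.09, adjusted p = 7.12e-10).

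Of 6 lists of immune cell markers, 3 fell in the same libraries, and those of dendritic cells, neutrophils and B cells did not pass. Of 16 microglia markers, a seeded cell type, 15 fell and 1 did not pass (median -5.38, -4.46 without the member at 0, adjusted p = 3.62e-06). Tmem119 went from 2027 ± 158 to 103 ± 33.6 (n = 3). Fcrls was listed at 0 in all 3 bioink libraries and at 1043, 1021 and 972 in the tumours. Markers of infiltrating macrophages and monocytes, which the labels do not name as seeded, fell in 13 of 15 cases and rose in 1. Their median was -4.13, or -3.95 without the member at 0 (camera adjusted p = 0.000239). Of 13 T and NK cell markers, 9 fell and 4 did not pass (median -2.88, -2.14 without the 3 members at 0, adjusted p = 0.0367; adjusted p = 0.114 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, stood at 32 ± 14.9 in tumours and 1 ± 1.73 in bioink (n = 3; log2 -4.29, -4.95 without bioink replicate 3, adjusted p = 0.000927).

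The lists of cholesterol synthesis, basement membrane, interstitial matrix and fibroblasts rose. Of 18 cholesterol synthesis genes, 16 rose and 2 did not pass (median 1.92, adjusted p = 3.05e-10), led by the synthase Hmgcs1, from 301 ± 22.1 to 2629 ± 234, and the sterol carrier Stard4, from 210.33 ± 46.1 to 1673 ± 74.3 (n = 3). Basement membrane genes rose in 12 of 14 cases and fell in 1 (median 1.244, adjusted p = 7.33e-06). Lama2, a laminin chain, went from 12 ± 2 to 450 ± 94.2 (n = 3). Col4a1, a chain of type IV collagen, went from 247 ± 226 to 3387 ± 401 (n = 3; log2 6.04, adjusted p = 0.0163, but log2 7.32, 7.60 and 3.21 without tumour replicate 1, 2 or 3). Col18a1 fell from 18488 ± 161 to 11004 ± 1169 (n = 3; log2 -0.75, adjusted p = 1.50e-05). Of 20 interstitial matrix genes, 13 rose, 5 fell (3 after quantile normalization) and 2 did not pass (median 2.46, adjusted p = 0.000496). The type I collagen gene Col1a1 rose 11.2-fold, from 662 ± 11.6 to 7449 ± 371 (n = 3; log2 3.49, SE 0.05, adjusted p = 8.37e-11). Fibroblast markers rose in 6 of 7 cases (median 4.00, adjusted p = 0.00381; adjusted p = 0.0504 with an estimated correlation).

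Genes of the unfolded protein response and of energy metabolism differed as well. Of 16 genes of the integrated stress and unfolded protein response, 15 fell (median -0.93, adjusted p = 1.71e-05), among them Sdf2l1, an endoplasmic reticulum chaperone cofactor, from 1186 ± 53.5 to 308 ± 14.7, and the pseudokinase Trib3, from 2646 ± 151 to 742 ± 19.2 (n = 3). Nuclear genes of oxidative phosphorylation fell in 15 of 18 cases and rose in 2 (median -0.79, adjusted p = 0.000944). Mitochondrially encoded genes rose in 8 of 10 cases and fell in 1 (median 2.12, adjusted p = 0.000114; adjusted p = 0.201 with an estimated correlation). In hypoxia and glycolysis, 13 of 21 genes rose and 4 fell, or 2 under the 3 other scalings (median 0.62, adjusted p = 0.00561; adjusted p = 0.269 with an estimated correlation). Vegfa, the endothelial growth factor, fell from 6216 ± 76 to 3718 ± 229.9 (n = 3; log2 -0.74, SE 0.05, adjusted p = 1.64e-06). Immediate early genes fell in 13 of 19 cases and rose in 3 (median -0.91, -0.58 after quantile normalization, adjusted p = 0.00802; adjusted p = 0.179 with an estimated correlation). Actin and SRF targets fell in 10 of 13 cases and rose in 1 (median -0.82, adjusted p = 0.0170; adjusted p = 0.0941 with an estimated correlation).

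Markers of the other seeded cells did not move as lists. Of 12 astrocyte markers, 6 rose and 3 fell (adjusted p = 0.118), with Gfap lower, at 594 ± 36.9 in tumours and 375 ± 17.8 in bioink (n = 3; log2 -0.66, adjusted p = 0.000641). Of 13 endothelial markers, 2 rose and 5 fell (adjusted p = 0.517), with Cdh5 higher, from 155 ± 27.1 to 607 ± 71.5 (n = 3; log2 1.97, adjusted p = 1.86e-06). Of 10 pericyte and mural markers, 4 rose and 3 fell (median -0.87, adjusted p = 0.986), with Pdgfrb higher, from 62.3 ± 28.3 to 209 ± 34.9 (n = 3; log2 1.80, adjusted p = 0.000434). Proliferation genes rose in 5 and fell in 13 of 24 cases (median -0.41, adjusted p = 0.229). Mki67, a marker of cycling cells, stood at 1765 ± 47.5 in tumours and 1830.3 ± 106 in bioink and was not called as deposited (n = 3; log2 0.05, adjusted p = 0.468), but was called higher under 3 other scalings (log2 0.16 to 0.23). P-selectin, encoded by Selp, stood at 23.3 ± 10.3 and 26.7 ± 7.09 and was not called (n = 3; log2 0.26, adjusted p = 0.678); without tumour replicate 3 the sign turned (-0.14). Mbp, a myelin protein, rose from 806 ± 44.5 to 2558 ± 146, and the inducible chaperone Hspa1a fell from 655 ± 35.8 to 221 ± 11 (n = 3 each; log2 1.66 and -1.56, adjusted p = 2.30e-08 and 0.00982).

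The remaining lists did not pass in this comparison. They were mesenchymal transition (6 of 14 higher, 2 lower, adjusted p = 0.0836), YAP and TEAD targets (4 of 14 higher, 9 lower, 0.118), matrix proteases and inhibitors (13 of 23 higher, 8 lower, 0.121), neurons (4 of 7 higher, 1 lower, 0.131), and angiogenic factors and receptors (7 of 18 higher, 6 lower, 0.326). Dendritic cells (1 of 6 higher, 3 lower) gave an adjusted p of 0.367, red blood cells (0 of 3 higher, 1 lower) 0.517, drug efflux and resistance (5 of 14 higher, 3 lower) 0.551, and glioma stem cell markers (5 of 13 higher, 5 lower) 0.592. Oligodendrocytes (4 of 11 higher, 4 lower) gave 0.610, neutrophils (1 of 3 higher, 1 lower) 0.615, B cells (0 of 3 higher, 1 lower) 0.630, ependyma and choroid plexus (0 of 4 higher, 1 lower) 0.775, heat shock (5 of 13 higher, 7 lower) 0.803, and selectins and their ligands (2 of 8 higher, 3 lower) 0.909. Median, mean and camera direction differed in sign for drug efflux, glioma stem cell markers, oligodendrocytes, neutrophils, selectins and pericytes. The neuronal gene Snap25 was too low to test, with 6, 0 and 0 in the tumour libraries, 0, 0 and 2 in 2D culture and 14, 5 and 10 in bioink.

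Across all 13773 genes tested with limma, 8869 (64.4%) were called, 3737 higher and 5132 lower in the bioink. The larger side turned under other scalings, with 4435 higher and 4229 lower after quantile normalization and 4520 higher and 4193 lower at equal upper quartiles. At least 2-fold, 1958 were higher and 2152 lower. The groups did not overlap for 67.7% of genes, against 10% by chance. Of 38 lists, 19 passed with camera, 6 higher and 13 lower; 11 of them held with an estimated correlation. Fry passed 36 of all 38, too many to set these 19 apart. Adjusted over the list alone, 13 MHC class I genes, 10 checkpoint genes and 14 proliferation genes were lower, and all other counts were as given. The median log2 fold change of all genes was -0.11 as deposited and between -0.01 and 0.07 under 3 other scalings, and no list that passed changed sign under them.

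The comparison of 2D culture with tumours asked the same for the penta-culture on a dish. Interferon, cytokine, antigen presentation and immediate early genes were far lower in the dish, and proliferation, cholesterol synthesis, basement membrane and interstitial matrix genes were higher. Cd74 fell from 64270 ± 2980 to 5 ± 2.65 (n = 3), a log2 fold change of -13.47 (SE 0.28, adjusted p = 3.90e-10). Fbln2, an extracellular matrix glycoprotein (chromosome 6, 91212460 to 91272540), rose from 10.7 ± 8.33 to 8605 ± 298 (n = 3), 877-fold higher (log2 9.78, SE 0.40, adjusted p = 3.23e-08). Lox rose from 8.67 ± 8.51 to 2170.3 ± 16.2 (n = 3; log2 8.59, adjusted p = 1.36e-05), with 7.34 without tumour replicate 1 and 9.42 without replicate 3.

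The other 3 genes with the largest rises were listed at 0 in all 3 tumour libraries. In the 2D libraries Msln, a surface protein of mesothelium, was listed at 321, 650 and 342, Prl2c2, of the prolactin family, at 268, 237 and 318, and the keratin Krt19 at 199, 228 and 239. Among the largest falls, C1qa was listed at 0 in all 3 2D libraries and at 10750, 9620 and 9084 in tumours. Ctss, a lysosomal protease of antigen-presenting cells, fell from 34133 ± 133 to 4.67 ± 3.06, Il1b from 8636 ± 251 to 0.333 ± 0.577 and C1qc from 10685 ± 266 to 1.33 ± 1.16 (n = 3 each). Their log2 fold changes were -12.70, -12.74 and -12.33. The size of these falls depends on the 1 added before taking logs, because the 2D values were near 0.

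All 19 immediate early genes, which are induced within minutes of a stimulus, fell in 2D culture (median -3.29, adjusted p = 2.86e-14). Fos (chromosome 12, 85473890 to 85477274) went from 34802 ± 383 to 745 ± 46.2 (n = 3), 46.7-fold lower (log2 -5.55, SE 0.06, adjusted p = 8.65e-12). Fosb went from 8699 ± 275 to 20 ± 17.4 (n = 3; log2 -9.09, adjusted p = 3.04e-07), with -9.75 without 2D replicate 1 and -8.38 without replicate 2. Hspa1a fell from 655 ± 35.8 to 32.7 ± 19.1 (n = 3; log2 -4.51, -3.88 without 2D replicate 1, adjusted p = 1.24e-05), while heat shock genes as a list did not pass (7 of 13 higher, 5 lower, adjusted p = 0.630).

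All 21 interferon response genes fell (median -2.32, adjusted p = 1.14e-13), among them Gbp2, an interferon-induced GTPase, from 22492 ± 295 to 731 ± 22.3, and Cxcl9, from 1579 ± 77.7 to 2.67 ± 1.16 (n = 3). All 21 cytokines and chemokines fell (median -6.58, -6.10 without the 4 members at 0, adjusted p = 8.21e-12), with Tnf going from 2460.3 ± 39.5 to 1 ± 1 (n = 3). All 13 MHC class I genes fell (median -3.97, adjusted p = 2.64e-11), with H2-Q4 going from 11598 ± 339.9 to 348 ± 43.4 and Nlrc5 from 1579 ± 877 to 43.3 ± 26.1 (n = 3). All 8 MHC class II genes fell (median -7.28, -9.43 without the 2 members at 0, adjusted p = 1.73e-06). Complement genes fell in 12 of 13 cases and rose in 1 (median -6.59, -6.25 without the member at 0, adjusted p = 7.14e-09). Checkpoint genes fell in 10 of 12 cases (median -5.09, -4.81 without the member at 0, adjusted p = 1.90e-05), with Cd274 going from 4411 ± 139.5 to 105 ± 9.02 (n = 3; log2 -5.38, adjusted p = 1.21e-10). After quantile normalization the median was -5.96 for cytokines and -4.41 for checkpoint genes.

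Of 6 lists of immune cell markers, 5 fell in the same libraries, and B cell markers, lower in 2 of 3 cases, did not pass (adjusted p = 0.297). All 15 macrophage and monocyte markers fell (median -5.92, -5.72 without the 2 members at 0, adjusted p = 3.92e-09), with the arginase Arg1 going from 8251 ± 100.5 to 5 ± 1.73 and the lysozyme Lyz2 from 16210 ± 283 to 50.7 ± 15.57 (n = 3). Of 16 microglia markers, 15 fell (median -5.98, -4.48 without the 2 members at 0, adjusted p = 6.04e-09), with Tmem119 at 2027 ± 158 in tumours and 79.7 ± 9.45 in 2D culture (n = 3; log2 -4.66, adjusted p = 6.76e-08). T and NK cell markers fell in 12 of 13 cases (median -3.995, -3.74 without the 3 members at 0, adjusted p = 0.000351), with Cd3e at 0.333 ± 0.577 in 2D culture (n = 3). Dendritic cell markers fell in 5 of 6 cases (median -2.42, -1.72 without the 2 members at 0, adjusted p = 0.0289; adjusted p = 0.109 with an estimated correlation). Neutrophil markers fell in 2 of 3 cases (median -2.999, adjusted p = 0.0346; adjusted p = 0.125 with an estimated correlation). Without 3D bioink replicate 1, an alternative chosen after seeing the data, the neutrophil list gave an adjusted p of 0.0505. Only 3 of its 10 markers were tested. Among them was Lcn2, whose log2 fold change against tumours was -3 in 2D culture but 6.05 in bioink. After quantile normalization the median was -3.41 for T and NK cells, -1.63 for dendritic cells and -2.36 for neutrophils.

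Proliferation genes rose in 22 of 24 cases (median 1.13, adjusted p = 1.41e-10), with the mitotic kinase Bub1 going from 109 ± 24.3 to 553 ± 22.3 and the cyclin Ccne2 from 77.7 ± 22.1 to 339 ± 10.1 (n = 3). Mki67, at 1923 ± 59.1 in 2D culture, was among those not called (n = 3; log2 0.12, adjusted p = 0.106), but passed without bioink replicate 1 (adjusted p = 0.0412). Cholesterol synthesis genes rose in 16 of 18 cases (median 1.2, adjusted p = 1.85e-08). Basement membrane genes rose in 11 of 14 cases and fell in 2 (median 1.08, adjusted p = 9.90e-05). Interstitial matrix genes rose in 12 of 20 cases and fell in 6 (median 0.93, adjusted p = 0.00371), with Col1a1 going from 662 ± 11.6 to 5345 ± 64.0 (n = 3; log2 3.01, SE 0.05, adjusted p = 9.97e-11). Matrix proteases and their inhibitors fell in 14 of 23 cases and rose in 5 (median -0.96, -1.03 without the member at 0, adjusted p = 0.00457; adjusted p = 0.107 with an estimated correlation). The integrated stress and unfolded protein response fell in 11 of 16 cases and rose in 4 (median -0.96, adjusted p = 0.00561; adjusted p = 0.135 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 10 cases and fell in 2 (median 1.18, adjusted p = 0.0312; adjusted p = 0.439 with an estimated correlation).

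Among markers of seeded cells, endothelial genes fell in 8 of 13 cases and rose in 1 (median -0.94, -0.84 without the member at 0, adjusted p = 0.0246; adjusted p = 0.0981 with an estimated correlation). The member that rose was Cdh5, from 155 ± 27.1 to 592 ± 19.6 (n = 3; log2 1.94, adjusted p = 2.23e-06). Pericyte and mural markers were lower in 6 of 10 cases and higher in 2 but did not pass as a list (adjusted p = 0.0502), with Pdgfrb higher, at 149 ± 21.8 (n = 3; log2 1.32, adjusted p = 0.00380). Astrocyte markers were higher in 6 and lower in 4 of 12 cases (adjusted p = 0.678), with Gfap lower, at 166 ± 19.2 (n = 3; log2 -1.83, adjusted p = 6.12e-07). Vegfa fell from 6216 ± 76 to 1160.3 ± 27.3, Selp from 23.3 ± 10.3 to 4 ± 1.73, and Mbp rose from 806 ± 44.5 to 5658 ± 169.5 (n = 3 each; log2 -2.42, -2.23 and 2.81, adjusted p = 6.14e-10, 0.00431 and 6.14e-10). Adjusted p lay between 0.131 and 0.895 for the other lists, among them hypoxia and glycolysis (8 of 21 higher, 11 lower, 0.201), fibroblasts (3 of 7 higher, 1 lower, 0.246) and nuclear oxidative phosphorylation (6 of 18 higher, 1 lower, 0.367). Median, mean and camera direction differed in sign for drug efflux, heat shock, glioma stem cell markers and actin and SRF targets.

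**Figure D1:**
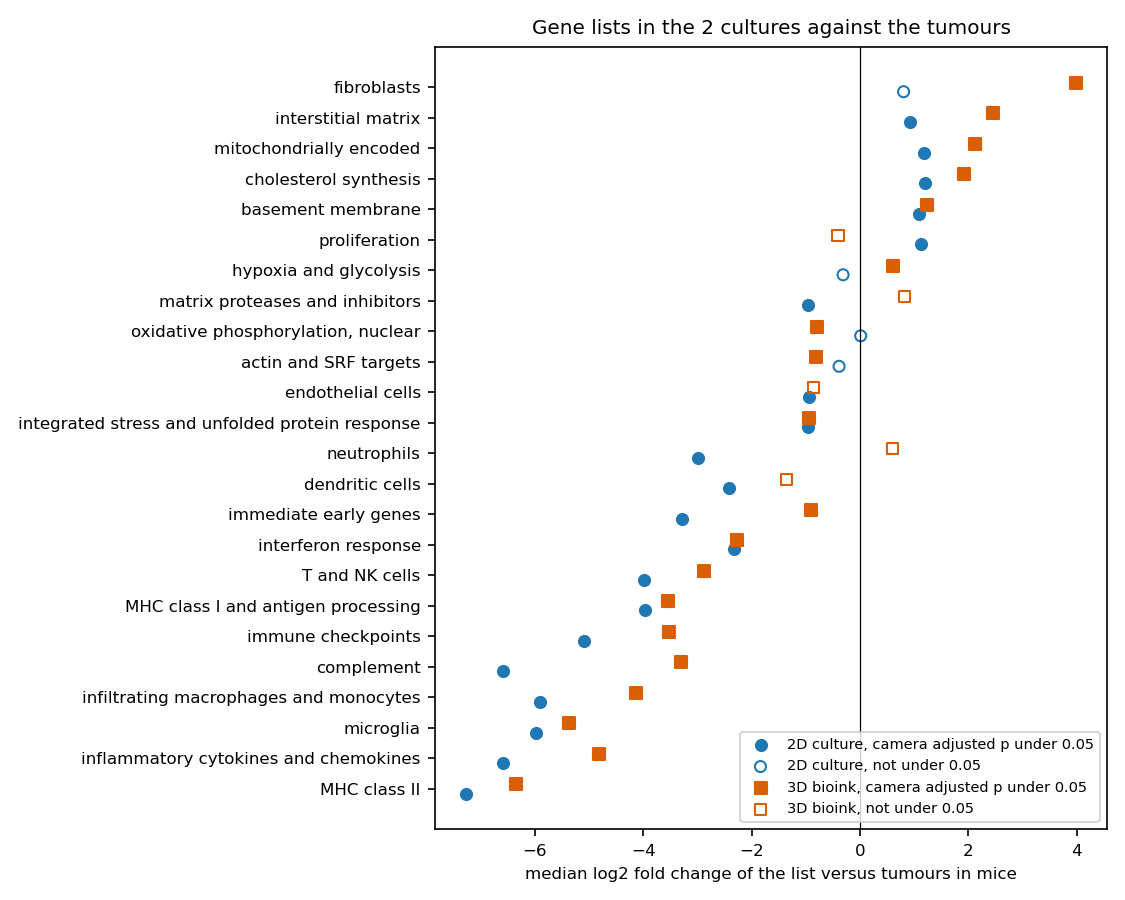
Median log2 fold change of each gene list in 2D culture (circles) and 3D bioink (squares) against the tumours in mice, for the lists that passed camera in at least 1 of these comparisons; filled symbols have an adjusted p under 0.05. Each point is a median over the list's tested members from 3 libraries per group, members listed at 0 included, and immune lists lie farthest below 0, down to -7.28 for MHC class II in 2D culture.

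Limma called 7474 of 13773 genes (54.3%) in 2D culture against tumours, 3761 higher and 3713 lower. Quantile normalization gave 4489 higher and 3058 lower. At least 2-fold, 1243 were higher and 2033 lower. The groups did not overlap for 63.9% of genes, against 10% by chance. Of 38 lists, 20 passed, 5 higher and 15 lower; 14 of them held with an estimated correlation. Fry passed 35 of all 38. Adjusted over the list alone, 23 proliferation and 17 cholesterol genes were higher, 3 neutrophil, 2 red blood cell, 7 YAP and TEAD and 6 actin and SRF genes were lower, and all other counts were as given or as over all genes. Quantile normalization moved the median of all genes from 0.01 to 0.18, and no list that passed changed sign.

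The comparison of the cultures asked how the penta-culture differed between fibrin and dish. Collagenase digestion and a mesh filter are recorded for the bioink only. For every gene in this comparison, growth in fibrin therefore cannot be told apart from this handling. In the bioink, immediate early genes, cytokines, complement and proteases were higher, and proliferation and nuclear oxidative phosphorylation genes were lower. Lcn2, the acute-phase protein lipocalin 2 (chromosome 2, 32384637 to 32387739), stood at 23 ± 6.08 in 2D culture and 12508 ± 1422 in bioink (n = 3), 529-fold higher (log2 9.05, SE 0.17, adjusted p = 7.12e-10). Its mean in tumours was 188 ± 17.6 (n = 3). The central complement component C3 rose from 8 ± 2 to 3572 ± 409.5 (n = 3; log2 8.65, SE 0.15, adjusted p = 4.10e-10), beside 10800 ± 261 in tumours.

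Fosb, Mmp3 and Nos2, the inducible nitric oxide synthase, completed the largest rises. Fosb went from 20 ± 17.4 to 6264 ± 327, Mmp3 from 15 ± 7.21 to 5823 ± 146 and Nos2 from 0.667 ± 1.16 to 496 ± 58.8 (n = 3 each; log2 8.61, 8.60 and 8.42). For Fosb this was 9.28 without 2D replicate 1 and 7.91 without replicate 2. Among the largest falls, Thoc7, of the THO complex for mRNA export, went from 135 ± 16.7 to 2.33 ± 4.04, and the keratin Krt80 from 233 ± 33.5 to 9 ± 13.1 (n = 3; log2 -6.08 and -5.65, adjusted p = 9.67e-05 and 0.000464). Thoc7 was at -7.08 without bioink replicate 3, and Krt80 at -6.86 without replicate 1 and -4.54 without replicate 2. Msantd4, Fech and Nme6 were listed at 0 in all 3 bioink libraries. In the 2D libraries Msantd4 was listed at 399, 419 and 754, the ferrochelatase gene Fech at 487, 184 and 403, and Nme6 at 98, 124 and 155.

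All 19 immediate early genes rose in the bioink (median 2.67, adjusted p = 1.14e-13), with Fos going from 745 ± 46.2 to 12420 ± 590.1 and Egr2 from 34.7 ± 4.93 to 765 ± 26.8 (n = 3; log2 4.06 and 4.43, adjusted p = 1.12e-10 and 6.79e-09). Digestion with collagenase is recorded only for the bioink libraries. Hspa1a rose from 32.7 ± 19.1 to 221 ± 11 (n = 3; log2 2.95, 2.32 without 2D replicate 1, adjusted p = 0.000237), and the heat shock list did not pass (3 of 13 higher, 5 lower, adjusted p = 0.626).

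Of 21 cytokines and chemokines, 17 rose and 4 did not pass (median 1.92, also without the 4 members at 0, adjusted p = 1.44e-06). The growth factor Csf3 went from 0.667 ± 1.16 to 74 ± 17.4 and the chemokine Cxcl1 from 12.3 ± 6.66 to 501 ± 61.5 (n = 3; log2 5.68 and 5.38). Complement genes rose in 11 of 13 cases and fell in 1 (median 2.61, 2.58 without the member at 0, adjusted p = 3.87e-05), with C4b going from 168 ± 37.8 to 5336 ± 280, while the anaphylatoxin receptor C3ar1 fell from 81 ± 6.56 to 24 ± 9.54 (n = 3; log2 5.00 and -1.77). Macrophage and monocyte markers rose in 11 of 15 cases and fell in 1 (median 1.41, also without the 2 members at 0, adjusted p = 0.000739). After quantile normalization 7 rose and 1 fell (median 0.565). Of 14 genes of all myeloid cells, chosen after seeing the data, 9 were higher in bioink and 0 lower. Among them, Tyrobp had means of 0 in both cultures, and Spi1 of 3.67 in 2D culture and 3.33 in bioink. The rise of the macrophage list therefore does not show that bioink held more macrophages. Microglia markers rose in 6 of 16 cases, and 10 did not pass (median 0.90, 0.80 without the 3 members at 0, adjusted p = 0.0303; adjusted p = 0.192 with an estimated correlation). For microglia markers quantile normalization gave 4 higher and 2 lower (median 0.561). Without bioink replicate 1, an alternative chosen after seeing the data, 9 were higher. Some of these markers lay near 0 in both cultures, such as C1qc at 1.33 ± 1.16 in 2D culture and 8 ± 4.58 in bioink (n = 3). Tmem119 was not called (79.7 ± 9.45 and 103 ± 33.6, n = 3; log2 0.32, adjusted p = 0.221), its sign turned with array weights (-0.03), and it passed without bioink replicate 3 (0.52, adjusted p = 0.0496). Cd274 rose from 105 ± 9.02 to 206 ± 7.81 (n = 3; log2 0.96, adjusted p = 1.24e-05), and the checkpoint list did not pass (5 of 12 higher, 2 lower, adjusted p = 0.201).

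Matrix proteases and their inhibitors rose in 19 of 23 cases (median 1.237, adjusted p = 1.95e-07), with the collagenase Mmp13 going from 5.67 ± 3.51 to 550.33 ± 33.9 (n = 3; log2 6.53, adjusted p = 4.51e-07). The inhibitor Timp2 was the member that fell, from 9411 ± 685 to 5455 ± 139 (n = 3; log2 -0.78, adjusted p = 7.59e-05). Mesenchymal transition genes rose in 10 of 14 cases and fell in 2 (median 1.07, adjusted p = 0.00421). Interstitial matrix genes rose in 13 of 20 cases and fell in 3 (median 0.57, adjusted p = 0.00895; adjusted p = 0.0561 with an estimated correlation), with Col1a1 going from 5345 ± 64.0 to 7449 ± 371 (n = 3; log2 0.48, SE 0.05, adjusted p = 2.32e-05). Actin and SRF targets fell in 9 of 13 cases (median -0.92, adjusted p = 0.000991). Cholesterol synthesis genes rose in 12 of 18 cases and fell in 1 (median 0.37, 0.57 after quantile normalization, adjusted p = 0.000985).

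Proliferation genes fell in 23 of 24 cases (median -1.47, adjusted p = 7.46e-11). Rrm2, a subunit of ribonucleotide reductase, went from 2641 ± 60.1 to 676 ± 20.6, and the mitotic kinase Plk1 from 2163 ± 134 to 569 ± 95.7 (n = 3; log2 -1.96 and -1.94). Mki67 was the member not called (1923 ± 59.1 and 1830.3 ± 106, n = 3; log2 -0.07, adjusted p = 0.319), and its sign turned under 3 other scalings (0.02, 0.10 and 0.13). Hypoxia and glycolysis genes rose in 14 of 21 cases and fell in 1 (median 0.87, adjusted p = 9.28e-06; adjusted p = 0.109 with an estimated correlation). The carbonic anhydrase Car9 went from 37.7 ± 12.2 to 627 ± 48.3 and Ndrg1 from 68 ± 12.8 to 506 ± 44.2, while the glycolytic enzyme Eno1 fell from 36019 ± 802 to 26876 ± 1427 (n = 3; log2 4.07, 2.89 and -0.42). Vegfa rose from 1160.3 ± 27.3 to 3718 ± 229.9 (n = 3; log2 1.68, SE 0.05, adjusted p = 1.73e-08). Nuclear oxidative phosphorylation genes fell in 17 of 18 cases (median -0.74, adjusted p = 3.62e-06), with Sdhb, of complex II, going from 2542 ± 56.0 to 1105 ± 17 and Uqcrc1, of complex III, from 610 ± 11.3 to 269 ± 27.2 (n = 3). Mitochondrially encoded genes rose in 9 of 10 cases (median 0.93, adjusted p = 0.000316; adjusted p = 0.233 with an estimated correlation), with ND2 going from 5470.3 ± 126 to 13632 ± 3787 and ND4 from 7449 ± 252 to 17579 ± 4922 (n = 3).

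Some cell type markers also differed between the cultures. Fibroblast markers rose in 5 of 7 cases and fell in 1 (median 1.92, adjusted p = 0.0466; adjusted p = 0.135 with an estimated correlation), and the list gave an adjusted p of 0.0709 without bioink replicate 1, an alternative chosen after seeing the data. Astrocyte markers rose in 6 of 12 cases and fell in 1 (median 0.44, adjusted p = 0.0300; adjusted p = 0.107 with an estimated correlation), with Gfap going from 166 ± 19.2 to 375 ± 17.8 (n = 3; log2 1.17, adjusted p = 1.56e-05). Neuronal genes rose in 4 of 7 cases (median 1.45, adjusted p = 0.0232; adjusted p = 0.282 with an estimated correlation). The MHC class II list did not pass (4 of 8 higher, 0 lower, adjusted p = 0.0502), but gave an adjusted p of 0.0379 without bioink replicate 1. Pericyte and mural markers (5 of 10 higher, 1 lower, adjusted p = 0.0539) and endothelial markers (5 of 13 higher, 2 lower, adjusted p = 0.156) did not pass. Pdgfrb (log2 0.48, adjusted p = 0.185) and Cdh5 (log2 0.03, adjusted p = 0.877) were not called, Pdgfrb passed with array weights (0.67, adjusted p = 0.0130), and the sign of Cdh5 turned without bioink replicate 2 (-0.03) or 3 (-0.02). Cd3e was not called (log2 0.33, adjusted p = 0.736), and its sign turned without bioink replicate 3 (-0.33) and under quantile normalization (-0.17). Selp rose from 4 ± 1.73 to 26.7 ± 7.09, and Mbp fell from 5658 ± 169.5 to 2558 ± 146 (n = 3; log2 2.49 and -1.15, adjusted p = 0.00212 and 3.21e-07). For interferon response, 9 of 21 genes rose and 7 fell (median 0.00, adjusted p = 0.775), and for basement membrane 5 of 14 rose and 4 fell (adjusted p = 0.803). Median, mean and camera direction differed in sign for B cells, red blood cells and glioma stem cell markers.

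**Figure D2:**
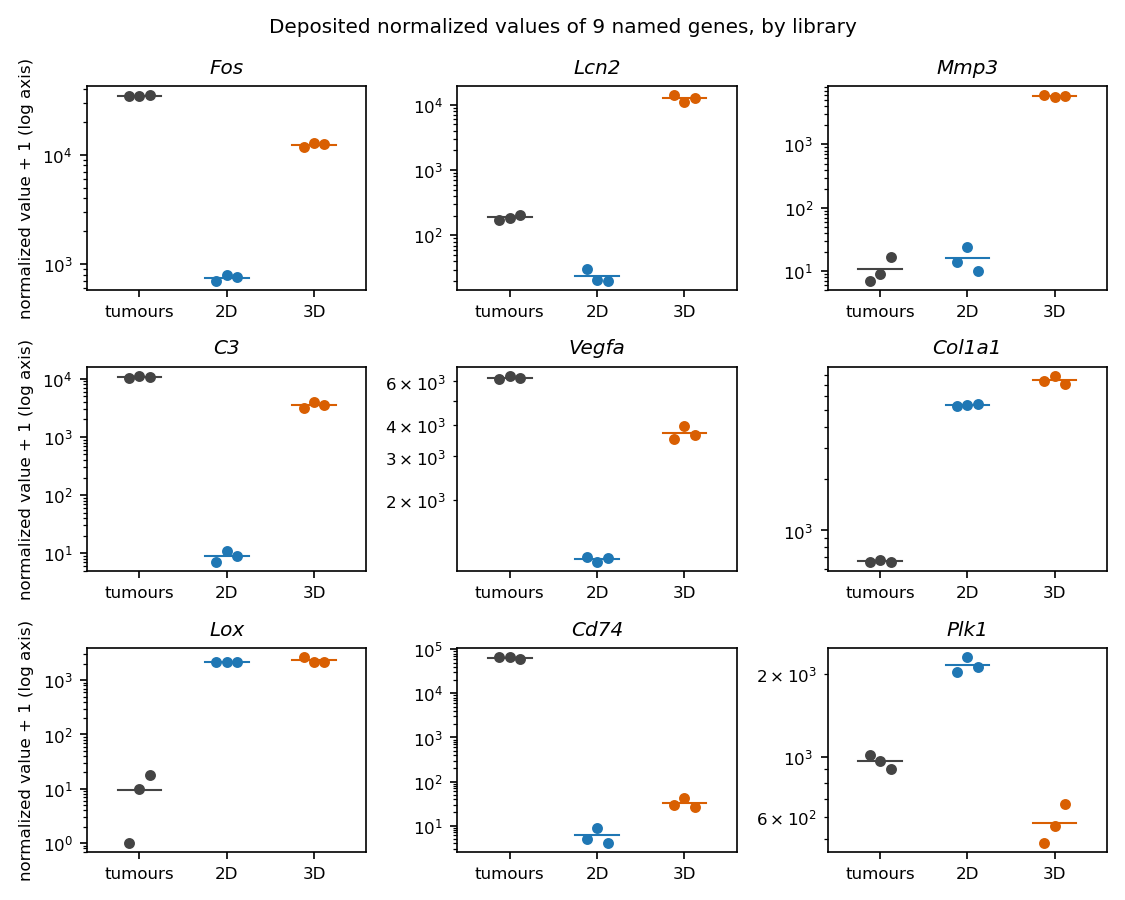
Deposited normalized values plus 1 on log axes for 9 named genes, with 1 point per library, short lines at the group means, and the groups tumours in mice, 2D culture and 3D bioink on the horizontal axis. Lcn2 stood at 23 ± 6.08 in 2D culture and 12508 ± 1422 in bioink, and Cd74 at 64270 ± 2980 in tumours and 32 ± 7.94 in bioink (mean ± SD, n = 3).

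Limma called 8148 of 13773 genes (59.2%) between the cultures, 3713 higher and 4435 lower in the bioink. At least 2-fold, 1985 were higher and 1503 lower. With libraries rescaled to the same upper quartile, 4528 were higher and 3585 lower, with median of ratios 4181 and 3966, and at equal upper quartiles the median log2 fold change of all genes moved from -0.02 to 0.14. The groups did not overlap for 67.1% of genes, against 10% by chance. Of 38 lists, 17 passed, 14 higher and 3 lower; 10 of them held with an estimated correlation. Fry passed 34 of all 38. Adjusted over the list alone, 15 hypoxia and 13 cholesterol genes were higher, 3 MHC class I and 8 interferon genes were lower, and all other counts were as given or as over all genes.

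Both cultures were set against the tumours to see which lay nearer. Of the 8148 genes called between the cultures, 3375 (41.4%) had a bioink mean nearer the tumour mean and 4773 had a 2D mean nearer. Among those that differed at least 2-fold, 1580 were nearer in bioink and 1908 in 2D culture. The root mean square log2 distance to the tumours was 1.80 ± 0.0154 for 2D culture and 1.73 ± 0.124 for bioink (n = 3 each). The difference of 0.0629 did not pass an exact two-sided permutation test (p = 0.4, smallest possible 0.1). By library the bioink distances were 1.88, 1.65 and 1.67, and each tumour library lay 0.807 to 0.827 from the mean of the others. The difference was 0.134 (exact p = 0.1) without bioink replicate 1, 0.0227 without replicate 2 and 0.032 without replicate 3. Its sign turned with no filter (-0.00655), with quantile normalization (-0.0389) and with distances from Pearson (-0.0190) or Spearman correlation (-0.0103), and it was 0.334 (exact p = 0.1) over the 2000 most variable genes.

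**Figure D3:**
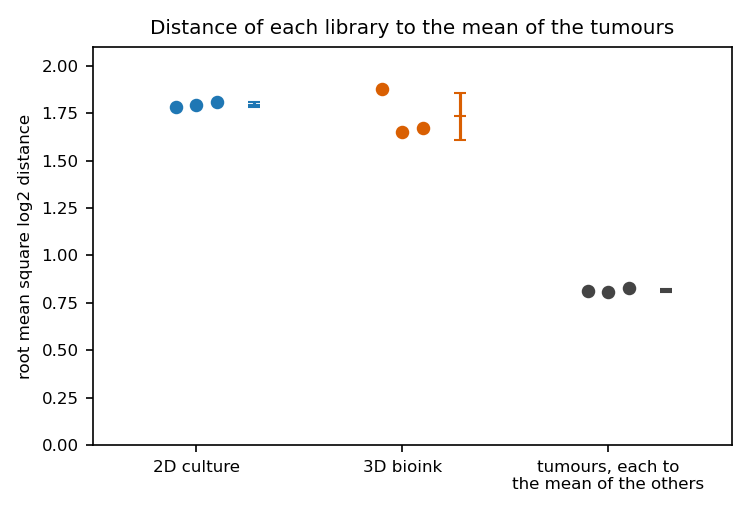
Root mean square log2 distance over 13773 genes of each library to the mean of the 3 tumour libraries, or for a tumour library to the mean of the other tumours; points are libraries, and the marks beside them are the mean with SD (n = 3). The bioink libraries lie at 1.88, 1.65 and 1.67, on both sides of the 2D libraries at 1.78, 1.80 and 1.81.

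The comparisons with the tumours shared many calls. In both cultures 2070 genes were higher than in tumours and 2406 lower, where independent lists would share 1020 and 1384. Simulated groups with no effect called on average 0 and 0.05 genes, so they could share none by construction and give no comparison for these counts. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.748 (0.501 simulated) and a covariance of 2.13 (0.127 simulated). The signs were the same for 65.7% of genes, against 66.7% in the simulation. With no tumour library in common, 1 for one culture and the other 2 for the other, an alternative chosen after seeing the data, the covariance was 1.98 and the correlation 0.652 to 0.659 over the 6 assignments. Part of the excess in the counts may come from the shared tumour libraries, since no split leaves 2 of them for each culture. Of genes also called between the cultures, 373 were higher in bioink and lower in 2D culture than in tumours, among them Lcn2 and Car9, and 858 were the reverse, among them Plk1.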

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

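The tests of explanations for 2 patterns weighed here were chosen only after the results were seen; the counts over other splits of the libraries were planned.

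Among genes taken by the rule for named genes, 5 differed from the tumours in opposite directions in bioink and in 2D culture. For each of them the difference between the cultures was itself called by limma. Lcn2 differed by 9.05 on the log2 scale (adjusted p = 7.12e-10), with 6.05 in bioink and -3 in 2D culture against tumours. Csf3 differed by 5.68 (adjusted p = 2.72e-05), with 3.60 and -2.08. The 2D values of Csf3 were near 0, so 5.68 and -2.08 depend on the 1 added before taking logs. Car9 differed by 4.07 (adjusted p = 4.36e-07), with 1.80 and -2.26, and Ndrg1 by 2.89 (adjusted p = 3.29e-07), with 0.47 and -2.42. Plk1 went the other way, with a difference of -1.94 (adjusted p = 5.16e-07), -0.76 in bioink and 1.17 in 2D culture. Fech and Msantd4 met the same criterion and were listed at 0 in all 3 bioink libraries. In the tumour and 2D libraries Fech was listed at 123, 74 and 91 and at 487, 184 and 403, and Msantd4 at 0, 94 and 112 and at 399, 419 and 754.

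The first pattern is the rise of all 19 immediate early genes in bioink over 2D culture. The scaling of the libraries as its whole source is argued against by the list's median, which was at least 2.63 under 4 scalings. Bioink replicate 1, which stood apart, is argued against as well, since 19 members stayed higher without it. Enzyme digestion before RNA isolation may have induced these genes (list median 2.67). It cannot be told apart from growth in fibrin, because digestion is recorded for every bioink library and for no other library. The tumours, for which no digestion is recorded, were higher than bioink for 13 of the 19 genes and lower for 3. The tumours differ from the cultures in cells and handling, so this does not decide the cause in bioink. An effect of the gel itself on the living cells also stays open, untested.

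The second pattern is the low level of microglia markers in both cultures, although microglia were seeded. The smallest fall of the list's median over 4 scalings and both cultures was -5.24, which argues against scaling as its whole source. Immune cells of the host may account for part of the difference. Markers of macrophages and monocytes were lower in 2D culture than in tumours by a median of -5.92. Their fall does not decide this, because microglia express some of these markers as well. The size of the difference cannot be divided between host cells in the tumours and a loss of seeded microglia, because the groups differ in host cells by design. A changed state of seeded microglia as the whole source is argued against by 14 genes of all myeloid cells, chosen after seeing the data. Their means were 377 to 7414 in tumours, 0 to 49 in 2D culture and 0 to 122 in bioink. Both cultures thus held little RNA of these genes, whatever host cells the tumours contained.

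Tmem38b, chosen after its values were seen, was among the 20 most abundant symbols and had unequal replicates in 2D culture (144899, 77829 and 48218). Its coefficient of variation was 54.9% in 2D culture, 36.5% in bioink and 6.79% in tumours, where symbols with a mean over 10000 had medians of 2.75%, 6.67% and 3.28%. Its annotated transcripts shared 89 stretches of 31 bases with a 5S ribosomal RNA. At least 31 such stretches were shared with a ribosomal RNA by 2 of the 20 most abundant symbols, the other being Gm20594 (42, mean 72474), and by 7 of 13701 others. Symbols that shared 74 to 84 with a 5S ribosomal RNA had lower means, among them 861 for Emc7, 464 for Hddc2, 1028 for Antxr1 and 1070 for Sp100, against 125633 for Tmem38b.

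Only 10 splits of the 6 libraries of a comparison into groups of 3 exist, too few for a share under 0.05. The real split called 8869 genes for bioink against tumours, 7474 for 2D culture against tumours and 8148 between the cultures, and the highest count of any other split was 1 in each. For the 4773 genes nearer the tumours in 2D culture the highest other split also gave 1. Every other split mixes libraries of both groups, which moves the group difference into the spread, so few genes could pass. The count nearer the tumours is taken among called genes and cannot exceed them. The other splits therefore give no comparison for these counts.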

How the results depend on the processing

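The alternatives reported here were planned, except for the distance with differences capped at 2-fold, the distance without mitochondrially encoded and 3 other symbols, and the lists without bioink replicate 1, which were chosen after seeing the data. All 102 called results for named genes kept their direction and their call in every alternative run for them. For results that were not called, Mki67 between the cultures turned to 0.0237 with median of ratios, 0.13 with quantile normalization and 0.10 with upper quartile scaling. Cd3e between the cultures turned to -0.17 with quantile normalization and ranged from -0.33 to 0.67 with a library left out. Tmem119 between the cultures turned to -0.03 with array weights, Cdh5 between the cultures ranged from -0.0273 to 0.131 with a library left out, and Selp in bioink against tumours from -0.14 to 0.53. Some results that were not called passed elsewhere: Mki67 in bioink against tumours with median of ratios (0.16), quantile normalization (0.23) and upper quartile scaling (0.23), Mki67 in 2D culture against tumours without bioink replicate 1 (adjusted p = 0.0412), Tmem119 between the cultures without bioink replicate 3 (adjusted p = 0.0496) and Pdgfrb between the cultures with array weights (0.67). The cause was not tested.

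The counts of genes kept within 1.5 times of the reported ones in the other settings, but a minimum of 2-fold lowered them by its construction. They then were 1958 higher and 2152 lower for bioink against tumours, 1243 and 2033 for 2D culture against tumours, 1985 and 1503 between the cultures, and 1580 nearer the tumours in bioink. The count nearer the tumours in bioink otherwise lay between 3024 and 4182 and was always below that for 2D culture. Leaving out a library kept 87.5% to 99.6% of the called genes, with 0 changes of sign.

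The difference in distance to the tumours turned under 5 alternatives, and the cause was not tested. It was -0.00655 with no filter (exact p = 1), -0.0389 with quantile normalization (exact p = 0.8), -0.0190 with Pearson correlation, -0.0103 with Spearman correlation and -0.0613 with differences capped at 2-fold (exact p = 0.1 for each of the last 3). Over the 2000 most variable genes it was 0.334, in the other direction, also with an exact p of 0.1. With a library left out it ranged from 0.0227 (without bioink replicate 2) to 0.134 (without bioink replicate 1), and it was 0.032 without bioink replicate 3. Without mitochondrially encoded genes and Gm20594, Tmem38b and Slc38a6 it was 0.0638. With a pseudocount of 5 it was 0.03435, and with a pseudocount of 0.5 it was 0.07354 (exact p = 0.4 for each).

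Deviations of same-numbered libraries had correlations of -0.033 to 0.08, and others -0.063 to 0.052, so no pairing by replicate number showed over all pairs. Between tumours and bioink, same-numbered pairs had 0.034, 0.048 and 0.08, above the others at -0.063 to 0.009. A shared preparation is therefore not excluded. With the replicate number as a block, 3356 genes were nearer the tumours in bioink, and no call for a named gene changed. Of 56 list calls, 35 held with an estimated correlation and 54 without bioink replicate 1; the others were neutrophils in 2D culture against tumours (0.0505) and fibroblasts between the cultures (0.0709). Fry passed 36, 35 and 34 of all 38 lists in the 3 comparisons, too many for its agreement to count for these calls. No list that passed changed the sign of its median under the 3 other scalings. The planned test on counts was not run, since the values are not counts. Read depth is unknown, and its effect on low values could not be measured.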

Other observations

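All gene lists and tests in this part were chosen after the data had been seen. Ribosomal protein genes were lower in bioink than in both other groups. Of 77 genes, 69 were lower than in tumours (median log2 fold change -0.98, camera adjusted p = 9.08e-13 over 27 tests; adjusted p = 0.132 with an estimated correlation). Against 2D culture 66 of 77 were lower (median -0.94, adjusted p = 2.11e-13; adjusted p = 0.128 with an estimated correlation). Between 2D culture and tumours 3 were higher and 20 lower, and the list did not pass (median -0.11, adjusted p = 0.0910). Replication-dependent histone genes, which cells transcribe in S phase, differed between the groups as well. Of 56, 47 were higher in 2D culture than in tumours (median 0.96, adjusted p = 1.85e-11), and 50 were lower in bioink than in 2D culture (median -1.64, adjusted p = 1.07e-14), both with an adjusted p of 0.0416 with an estimated correlation. Bioink was also lower than tumours for 34 of 56 (median -0.58, adjusted p = 0.000197; adjusted p = 0.152 with an estimated correlation).

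Lysosomal genes were lower in 2D culture than in tumours in 11 of 15 cases and higher in 1 (median -0.64, adjusted p = 0.000208). In bioink 10 of 15 were higher than in 2D culture and 3 lower (median 0.43, adjusted p = 0.00714; adjusted p = 0.105 with an estimated correlation). Genes of all myeloid cells were higher in bioink than in 2D culture in 9 of 14 cases (median 1.12, adjusted p = 0.00335; adjusted p = 0.0719 with an estimated correlation), and all 14 were lower than in tumours in bioink (median -6.72, adjusted p = 2.17e-07) and in 2D culture (median -8.08, adjusted p = 2.04e-10). The myeloid genes had low means in the cultures, 0 to 49 in 2D culture and 0 to 122 in bioink. Between the cultures Ptprc, Tyrobp, Spi1, Aif1 and Dock2 were not called. Tyrobp had means of 0 in both cultures, and Spi1 of 3.67 in 2D culture and 3.33 in bioink. The rise of the list therefore does not show that bioink held more myeloid cells. NRF2 targets, genes of the oxidative stress response, did not pass in any comparison (adjusted p = 0.870, 0.842 and 0.748).

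The rise of Lcn2 and C3 in bioink over 2D culture led to 2 hypotheses, each tested on a list without these genes. A reactive astrocyte programme may be part of it: of 12 genes induced in reactive astrocytes, 8 were higher in bioink and 1 lower (median 0.91, camera adjusted p = 0.0013; adjusted p = 0.12 with an estimated correlation). Serpina3n had means of 2721 in 2D culture and 38850 in bioink, Cp of 272 and 11380, and Osmr of 686 and 2396 (n = 3 each). The member that fell was Vim, with means of 67320 in 2D culture and 45700 in bioink. Timp1, Hspb1 and S1pr3 were not called. Among genes linked to neurotoxic reactive astrocytes 6 of 11 were higher and 1 lower (adjusted p = 0.0302; adjusted p = 0.155 with an estimated correlation), and among those linked to protective ones 4 of 11 were higher and 3 lower (adjusted p = 0.235). An NF-kB target programme may be part of it too: 9 of 14 targets were higher and 0 lower (median 1.21, camera adjusted p = 8.24e-05; adjusted p = 0.0416 with an estimated correlation). Nfkbia had means of 643 and 4195, and Tnfaip3 of 238 and 4868 (n = 3 each). Against tumours, 12 of these 14 targets were lower in bioink (median -1.63, adjusted p = 8.24e-05). In the same comparison, 8 of 11 neurotoxic astrocyte genes were lower and 1 higher (median -3.14, camera adjusted p = 0.0013). Of the 12 reactive astrocyte genes, 8 were higher and 2 lower (median 1.54, camera adjusted p = 0.00596). Camera with an estimated correlation gave adjusted p = 0.0746 and 0.152 for these astrocyte lists. These tests do not say which cells carried the change, nor whether digestion induced it.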
